A study of Mus musculus with 32 samples.

How the data were processed

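The series measured RNA of the mouse distal colon on Affymetrix expression arrays, with a single array for each of 32 mice. Per the labels, the mice were wild type (WT) or lacked Myd88 (knockout, KO), the adaptor protein that most Toll-like receptors and the IL-1 and IL-18 receptors signal through, on a congenic C57BL/6 background. Treated mice were injected with azoxymethane (AOM, a carcinogen that causes colon tumours in rodents) and later drank dextran sodium sulfate (DSS), which injures the colon lining. The groups were 10 treated WT, 10 treated KO, 6 untreated WT and 6 untreated KO mice. No batch, array date or sex was given, and the repeat numbers were not described as pairs.

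The deposited values were log2 probe set signals in a table of 45101 probe sets, 64 of them controls. The software that summarised the probes was not named in the sources used here. The values themselves showed that the authors had scaled each array: the 2% trimmed mean of the linear signals lay between 150.9 and 151.3 on every array. Signals under 10 had been raised to 10, a floor of 3.322 on the log2 scale, and between 18.7% and 23.9% of the probe sets of an array lay on it. Array medians differed (5.17 to 5.53), so the log2 values were quantile normalized before the tests. A floor hides differences among dim genes and makes a fold change against it too small. The brightest genes lie near the top of the scale of such arrays, where differences are compressed.

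Gene symbols came from the platform annotation and current gene names from a RefSeq gene table of the mouse. Of the probe sets, 34958 carried 1 symbol, 932 several and 9211 none. Each gene was represented by its probe set with 1 symbol and the highest mean signal, which gave 18193 genes. A linear model of the 4 group means over all 32 arrays was fitted with limma 3.58.1 in R 4.3.3, with moderated statistics (28 residual and 1.10 prior degrees of freedom). The contrasts were KO minus WT in treated mice, KO minus WT in untreated mice, treated minus untreated in each genotype, and the difference of the responses (interaction). Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. A change is given as a log2 difference ± its standard error. Precision is limited by the number of mice, by the spread between arrays and, for dim and bright genes, by the scale of the arrays.

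Before the data were examined, 41 gene lists of pathways and cell type markers were written down, and were tested with limma's camera at a preset correlation between genes of 0.01. The same test was run with an estimated correlation for each list, and fry was run beside it. Counts of called members are given over all genes and adjusted over the list alone. The genes named in the text were chosen by a rule fixed at the same time. It took the 6 largest rises and the 6 largest falls of each comparison (4 and 4 for the interaction), leaving out predicted genes and naming at most 1 immunoglobulin gene in each direction. It added, for lists that passed or had at least 3 called members, up to 3 called members and the brightest member that did not pass. It also took 18 core genes of inflammation, growth and repair, of which 14 had a usable named probe set and the others were not analysed here.

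Alternatives fixed in advance were centring each array on its median in place of quantile normalization, leaving out genes under the 40th percentile of mean signal, averaging the probe sets of a gene, testing each probe set, fitting the compared groups only, the repeat number as a block, array weights, a trended and robust prior, covariates for RNA integrity (the difference between 3' and 5' control probe sets, averaged over Gapdh and Actb) and for smooth muscle, stricter thresholds, and leaving out each array in turn. Chosen after the data were seen were the values as deposited, the squamous epithelium and skeletal muscle list means as covariates, a fit without treated WT repeats 1 and 2, and the Xist signal as a covariate. The pipeline was tested on simulated data of the same design with 100 genes changed 2-fold and 100 changed 4-fold in each contrast, drawn from genes above the 40th percentile of mean signal. It recovered between 84% and 100% of the genes changed 2-fold and between 98% and 100% of those changed 4-fold. Between 2.63% and 6.57% of its calls were false. The simulated noise was independent between genes, with a common spread for all groups and a single data set per contrast. These rates therefore do not cover correlated genes, unequal spread between groups, other tissue on some arrays or outlying arrays.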

Results

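The series asked how Myd88 shapes the early reaction of the distal colon to a regimen that leads to colitis-associated tumours. RNA was measured on 32 arrays. Treated mice received AOM at 10 mg/kg by intraperitoneal injection and, 1 week later, 2% DSS for 3 days (10 WT and 10 KO mice, aged 6 to 8 weeks). Untreated mice numbered 6 in each genotype. Arrays of a group correlated with r between 0.935 and 0.985 across genes. The level of Xist, the RNA that silences an X chromosome in females, was high on 16 arrays and low on 16, with equal numbers of both in each of the 4 groups.

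Myd88, measured by a single probe set, averaged 8.40 ± 0.11 log2 units (SD, n = 6) in untreated WT and 7.67 ± 0.11 (SD, n = 6) in untreated KO mice. After treatment it averaged 8.46 ± 0.12 (SD, n = 10) in WT and 8.00 ± 0.31 (SD, n = 10) in KO mice. KO minus WT was -0.73 ± 0.11 without treatment (adjusted p = 0.000925) and -0.46 ± 0.09 with it (adjusted p = 0.00104). The treated KO arrays ranged from 7.50 to 8.31 and so reached past the lowest treated WT array, at 8.26. The labels do not say which part of the gene was removed. Efhd2 and Ptp4a2, both called between the untreated genotypes, parted the 16 KO from the 16 WT arrays without overlap: Efhd2 lay between 8.83 and 10.3 in KO and between 11.5 and 11.9 in WT mice, and Ptp4a2 between 12.2 and 12.7 in KO and between 10.2 and 11.2 in WT mice.

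Some arrays carried high signals of squamous epithelium and skeletal muscle genes, which may come from neighbouring tissues. Their source was not tested. The mean signal of 12 squamous epithelium genes, such as keratins of skin and anal lining, was 11.6 in treated WT repeat 1 and 9.93 in treated WT repeat 2, against a median of 5.48 over all arrays. By group it was 7.42 ± 2.29 in treated WT (SD, n = 10), 5.801 ± 1.511 in treated KO (SD, n = 10), 5.22 ± 0.75 in untreated WT (SD, n = 6) and 5.41 ± 1.73 in untreated KO mice (SD, n = 6). The treated WT median was 7.43, while untreated WT arrays reached 5.94 and untreated KO arrays 8.36. In WT mice the squamous mean thus went with treatment, and as a covariate it may remove part of a treatment effect. The mean of 7 skeletal muscle genes was highest in treated WT repeat 4, at 10.4, and reached 9.66 in untreated WT repeat 3. The difference between 3' and 5' control probe sets of Actb, a sign of RNA integrity, was 0.45 ± 0.03 in untreated WT, 0.46 ± 0.09 in untreated KO, 0.38 ± 0.05 in treated WT and 0.33 ± 0.06 in treated KO mice. That of Gapdh ran the other way with treatment, at -0.42 ± 0.02, -0.48 ± 0.05, -0.40 ± 0.03 and -0.39 ± 0.04 in the same order, so the 2 controls do not agree on a difference in integrity. The 3'/5' covariate used below is their average.

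**Figure D1:**
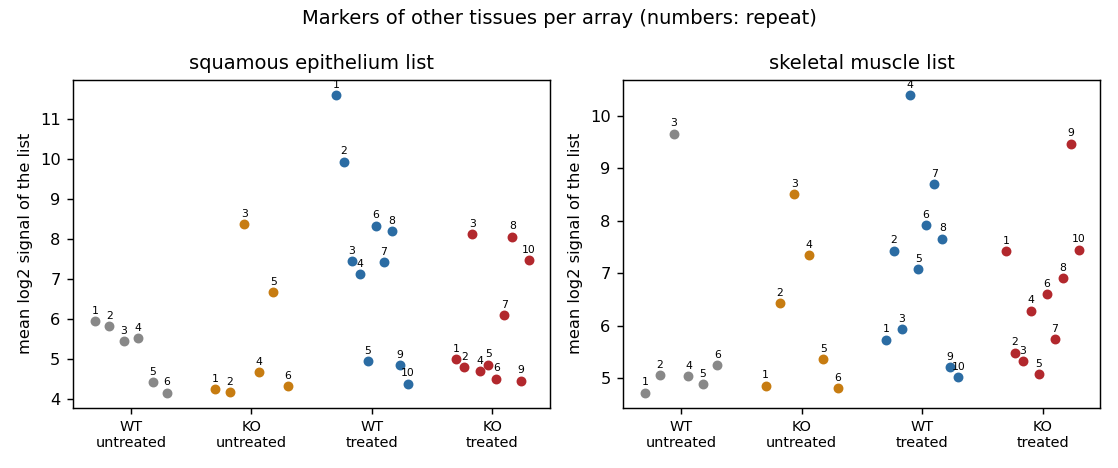
Mean log2 signal of the squamous epithelium list (left) and the skeletal muscle list (right) on each of the 32 arrays, by group, with points numbered by repeat. Treated WT repeat 1 stands highest on the left, at 11.6, and treated WT repeat 4 on the right, at 10.4.

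In WT mice, where the comparison asks what differed after AOM and DSS, genes of crypt stem cells and dividing cells fell while hormone genes of enteroendocrine cells rose. The labels give no protocol, age or housing for the untreated mice, so in both genotypes the regimen is not separated from other differences in handling. The list calls rest on the preset correlation between genes, and with an estimated one 0 lists passed. Ascl2, a transcription factor of intestinal stem cells, fell by 2.84 ± 0.44 (7.14-fold, adjusted p = 0.000895) and was at the floor on 3 of 10 treated arrays. Lgr5, a receptor that marks the same cells, fell by 1.86 ± 0.33 (adjusted p = 0.00293; by 1.06 with its probe sets averaged), and Smoc2 fell by 1.18 ± 0.25. Of the 18 measured crypt stem cell and Wnt target genes 5 fell and none rose (6 adjusted over the list alone), with a list median of -0.31 (camera adjusted p = 7.89e-05; adjusted p = 0.183 with an estimated correlation). All 30 genes of the mitotic cell cycle list were lower in treated WT mice, with a median of -0.64 (camera adjusted p = 9.77e-20; adjusted p = 0.190 with an estimated correlation). Of these, 13 fell over all genes tested and 20 adjusted over the list alone, among them Nusap1, a spindle protein (-0.99 ± 0.20, adjusted p = 0.00872). Pcna, the brightest mitotic gene that did not pass, was at -0.20 ± 0.12. With the 3'/5' difference as a covariate 5 mitotic genes passed, and with the squamous and skeletal muscle means 6, at medians of -0.59 and -0.73.

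Enteroendocrine markers rose in 3 of 10 cases in WT mice (4 adjusted over the list alone), with a list median of 0.42 (camera adjusted p = 5.11e-07; adjusted p = 0.227 with an estimated correlation). These were Gcg, the glucagon precursor (1.13 ± 0.20, adjusted p = 0.00321), Insl5 (0.87 ± 0.13, adjusted p = 0.000741) and Pyy (0.83 ± 0.14, adjusted p = 0.00258). Slpi, a secreted protease inhibitor, rose by 1.97 ± 0.42, or 3.92-fold, from 7.61 to 9.58 on average (adjusted p = 0.0126). Isx, an intestinal homeobox gene, rose by 2.25 ± 0.54, the chemokine gene Ccl8 by 1.83 ± 0.44 and Acacb, an acetyl-CoA carboxylase, by 1.73 ± 0.42. The largest falls besides those of stem cell genes were in Otc (-1.76 ± 0.37), a urea cycle enzyme, Scnn1g (-1.71 ± 0.26), a sodium channel subunit, the immunoglobulin gene Igkv6-20 (-1.67 ± 0.40) and Rgcc (-1.56 ± 0.33). The calls of Isx, Ccl8, Acacb and Igkv6-20 each ended without any 1 of 3 to 5 arrays, drawn from untreated WT repeats 1, 2, 4, 5 and 6 and treated WT repeat 7, at adjusted p up to 0.0722. With the 3'/5' covariate Isx (1.90), Ccl8 (1.55), Acacb (1.66) and Igkv6-20 (-1.64) did not pass, at adjusted p of 0.0537 or 0.0613. Acacb was at 1.28 with the squamous and skeletal muscle means as covariates (adjusted p = 0.161) and at 0.80 with its probe sets averaged (adjusted p = 0.0463), and passed in 35 of 44 settings. With the tissue means Slpi (1.70, adjusted p = 0.0545), Ccl8 (1.79, adjusted p = 0.0542) and Igkv6-20 (-1.46, adjusted p = 0.0989) did not pass either, and Otc was at -1.16 with its probe sets averaged.

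Clock genes also shifted in WT mice. Dbp fell by 1.35 ± 0.23 (adjusted p = 0.00258) and Per1 by 0.77 ± 0.15 (adjusted p = 0.00872), while Arntl, which works in opposite phase, rose by 0.60 ± 0.14 (adjusted p = 0.0256, lost without any 1 of treated WT repeat 7 and untreated WT repeats 1, 2, 4 and 6, at adjusted p up to 0.0726). Per1 was at -0.52 with the squamous and skeletal muscle means as covariates and Arntl at 0.35 with its probe sets averaged, and neither then passed (adjusted p = 0.0748 and 0.132). Of 14 clock genes 1 rose and 3 fell (2 and 7 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 0.000607; adjusted p = 0.190 with an estimated correlation). The labels give no hour of tissue collection. All 25 interferon-induced genes were higher in treated WT mice at a median of 0.37, but none passed over all genes and 4 did adjusted over the list alone (camera adjusted p = 3.55e-06; adjusted p = 0.436 with an estimated correlation). All 14 macrophage and monocyte markers were higher too, at a median of 0.44, with none called and 2 adjusted over the list alone (camera adjusted p = 1.52e-05; adjusted p = 0.432 with an estimated correlation). Lyz2, the brightest of them, differed by 0.79 ± 0.24 (adjusted p = 0.0923).

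The squamous list had a median of 2.14 in treated against untreated WT mice, with 1 of 12 members called and 8 adjusted over the list alone (camera adjusted p = 3.4e-07; adjusted p = 0.363 with an estimated correlation). The called member was Krt14, a basal keratin, which rose by 3.35 ± 0.90 (adjusted p = 0.0473) and reached 12.9 in treated WT repeat 1. Leaving out any 1 of 18 arrays ended that call, at adjusted p up to 0.121. These arrays were treated WT repeats 1, 2, 3, 4, 6 and 7, treated KO repeats 1, 2, 5, 7 and 8, untreated WT repeats 2 to 6, and untreated KO repeats 1 and 4. With the squamous and skeletal muscle means as covariates Krt14 was at 1.32 (adjusted p = 0.195), and without treated WT repeats 1 and 2 at 2.43 (adjusted p = 0.105). Skeletal muscle genes had a median of 1.66 with none called (camera adjusted p = 0.00721; adjusted p = 0.467 with an estimated correlation). Cxcl5, a neutrophil chemokine, rose by 1.96 ± 0.51 (adjusted p = 0.0405); it stood at 9.82 in treated WT repeat 2, with the other 9 treated WT arrays between 5.77 and 7.82. Its call ended without any 1 of treated WT repeats 2, 4, 6, 7 and 9 and untreated WT repeats 2 to 6, at adjusted p up to 0.107, and with the squamous and skeletal muscle means (1.64, adjusted p = 0.185).

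In all, 332 of 18193 genes changed in WT mice, 110 up and 222 down, and 75 of these by at least 2-fold (limma). The count fell to between 165 and 203 without any 1 of the 6 untreated WT arrays or without treated WT repeat 7. It was 185 with median centring, 159 with the 3'/5' covariate, 208 with the squamous and skeletal muscle means, and 1458 with array weights. In a fit of the WT arrays alone it was 888, where the KO response in a fit of the KO arrays alone gave 1918. The difference in size between the 2 responses thus depends on the spread shared over all groups.

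In KO mice the same regimen changed 3404 of 18193 genes (18.7%), 1581 up and 1823 down, and 382 by at least 2-fold. The share higher among them was 46.4%, against 65.4% with median centring and 39.1% with the values as deposited. The largest rises were in Clca4b (4.62 ± 0.80, 24.6-fold, adjusted p = 0.000215), Retnlb (4.28 ± 1.01, adjusted p = 0.00324), Slpi (3.38 ± 0.42, adjusted p = 5.28e-06), Dmp1 (3.00 ± 0.59), Sptssb (3.00 ± 0.88) and Lpcat4 (2.88 ± 0.38). Retnlb encodes a goblet cell protein of mucosal defence and Clca4b a chloride channel accessory protein. Cldn2, which encodes a tight junction protein that forms cation pores, fell by 4.11 ± 0.63 (17.3-fold, adjusted p = 6.28e-05), from 9.99 to 5.88 on average. The next largest falls were in Ascl2 (-2.97 ± 0.44), Nxpe2 (-2.68 ± 0.47), Cttnbp2 (-2.45 ± 0.41, and -1.32 with its probe sets averaged), the immunoglobulin gene Igkv6-14 (-2.42 ± 0.37) and Smpx (-2.36 ± 0.47). Ascl2 lay at the floor on most treated KO arrays, so its fall may be larger than shown.

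**Figure D2:**
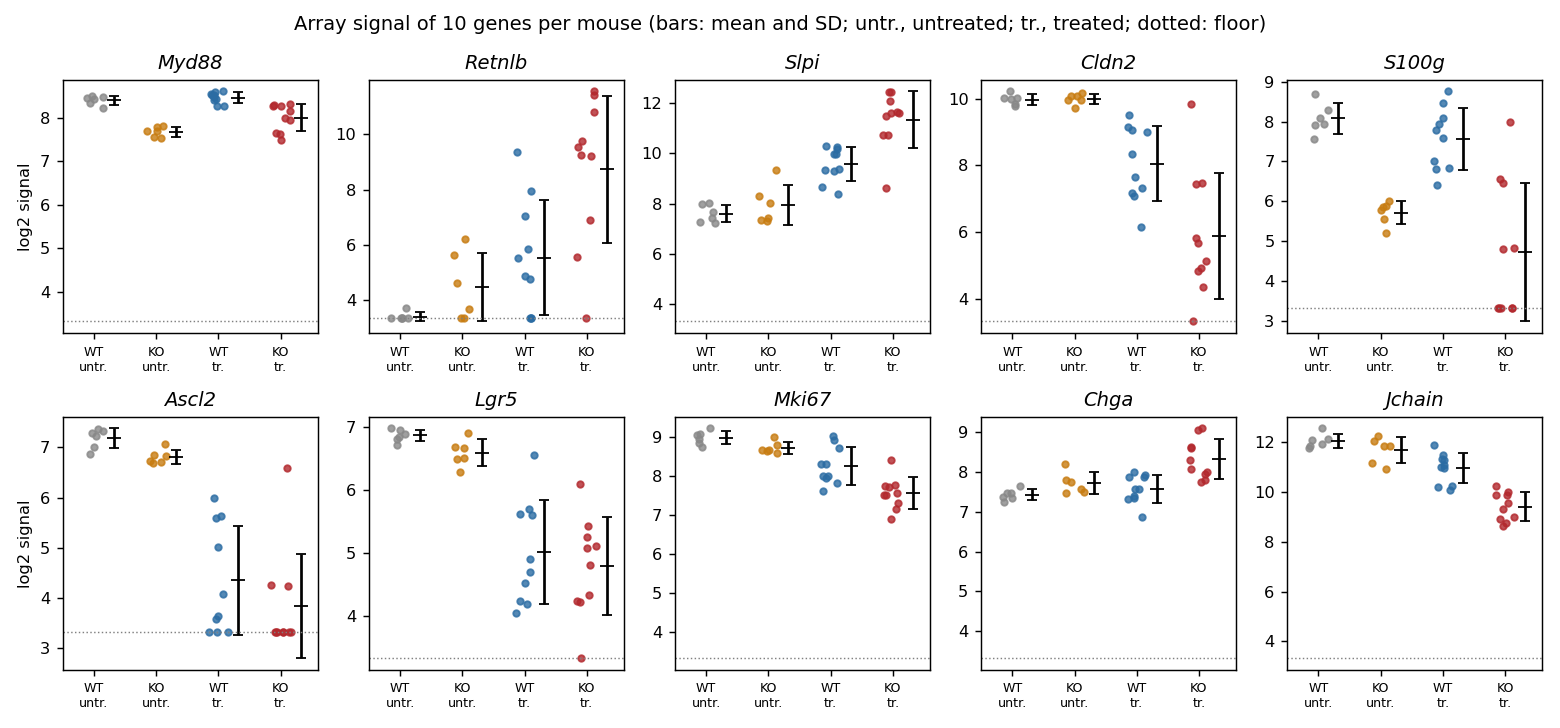
Log2 array signal of 10 genes in each mouse, with the mean and SD of each group (untreated WT and KO, n = 6; treated WT and KO, n = 10) beside the points and the floor of the values dotted. Cldn2 averaged 8.04 in treated WT and 5.88 in treated KO mice, and Retnlb 5.53 and 8.73.

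Dividing and stem cell genes fell in treated KO mice as well. Of 30 mitotic genes 19 fell (23 adjusted over the list alone), at a median of -0.87 (camera adjusted p = 8.5e-13; adjusted p = 0.223 with an estimated correlation). Ccnb2, a mitotic cyclin, fell by 1.59 ± 0.20, or 3.01-fold (adjusted p = 5.28e-06). Of 18 crypt stem cell and Wnt target genes 8 fell and 1 rose, over all genes and adjusted over the list alone. Their median was -0.33 (camera adjusted p = 0.000354; adjusted p = 0.125 with an estimated correlation), and the Wnt target Axin2 fell by 1.20 ± 0.18. DNA repair genes fell in 7 of 35 cases (8 adjusted over the list alone) at a median of -0.21 (camera adjusted p = 0.000198; adjusted p = 0.249 with an estimated correlation). Among them were Apex1 (-0.96 ± 0.18) and Ddb2 (-0.94 ± 0.18), which act in base and nucleotide excision repair. B and plasma cell markers fell in 4 of 12 cases, on both scales of adjustment, at a median of -0.74 (camera adjusted p = 0.000812; adjusted p = 0.288 with an estimated correlation). Jchain, the joining chain of secreted IgA and IgM, fell by 2.27 ± 0.27 (4.81-fold, adjusted p = 3.35e-06). In WT mice 3 of the 12 fell (4 adjusted over the list alone) and 6 were lower, at a median of -0.036, and the list did not pass (camera adjusted p = 0.0686; adjusted p = 0.504 with an estimated correlation). The 3 that fell were Jchain (-1.10 ± 0.27, adjusted p = 0.0283), Mzb1 (-1.09 ± 0.24, adjusted p = 0.0162) and Tnfrsf17 (-1.11 ± 0.28, adjusted p = 0.0362), which passed in 37 of 45, 44 of 45 and 31 of 44 settings. With the 3'/5' covariate Jchain (-1.07, adjusted p = 0.0613) and Tnfrsf17 (-1.15, adjusted p = 0.0584) did not pass. In KO mice Mzb1 fell by 1.67 ± 0.24, and Tnfrsf17 was at -0.35 ± 0.28 (adjusted p = 0.446). Distal Hox genes fell in 3 of 7 cases (4 adjusted over the list alone), Hoxd13 by 0.87 ± 0.15, at a median of -0.53 (camera adjusted p = 0.00905; adjusted p = 0.288 with an estimated correlation).

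Hormone, stress and inflammation lists rose in treated KO mice at the preset correlation, and with an estimated one 0 lists passed. Enteroendocrine markers rose in 9 of 10 cases, also adjusted over the list alone, at a median of 0.85 (camera adjusted p = 5.53e-10; adjusted p = 0.125 with an estimated correlation). Gcg rose by 1.57 ± 0.20 and Pyy by 1.35 ± 0.14, and Cck did not pass (0.46 ± 0.23). Interferon-induced genes rose in 9 of 25 cases (12 adjusted over the list alone) at a median of 0.61 (camera adjusted p = 6.22e-05; adjusted p = 0.364 with an estimated correlation), with Ifit1 at 1.86 ± 0.44 and Cxcl10 at 1.45 ± 0.25. Unfolded protein response genes rose in 8 and fell in 1 of 15 cases (9 and 2 adjusted over the list alone) at a median of 0.48 (camera adjusted p = 0.000164; adjusted p = 0.125 with an estimated correlation). Sdf2l1 led them at 0.97 ± 0.15. EGF receptor ligands and growth factors rose in 7 of 11 cases, also adjusted over the list alone, at a median of 0.50 (camera adjusted p = 0.00204; adjusted p = 0.125 with an estimated correlation); Ereg, the ligand epiregulin, rose by 1.88 ± 0.48. Cytokine and chemokine genes rose in 7 of 25 cases (8 adjusted over the list alone), with Cxcl5 at 2.53 ± 0.51, Il11 at 1.72 ± 0.42 and Cxcl2 at 1.33 ± 0.38, and a median of 0.49 (camera adjusted p = 0.000943; adjusted p = 0.226 with an estimated correlation).

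Immediate early genes rose in 6 of 15 cases (7 adjusted over the list alone), with Socs3, a feedback inhibitor of cytokine signalling, at 2.31 ± 0.53 and a median of 0.67 (camera adjusted p = 0.000417; adjusted p = 0.290 with an estimated correlation). Matrix remodelling genes rose in 4 of 10 cases (6 up and 1 down adjusted over the list alone) at a median of 0.81 (camera adjusted p = 0.00351; adjusted p = 0.288 with an estimated correlation); Mmp3, a matrix protease, rose by 1.90 ± 0.47. The list of IL-1 and IL-18 signalling, 2 pathways that run through Myd88, rose in 6 of 17 cases (6 up and 1 down adjusted over the list alone). Its median was 0.42 (camera adjusted p = 0.0087; adjusted p = 0.125 with an estimated correlation), and Il1rn, the IL-1 receptor antagonist, rose by 1.12 ± 0.14. Toll-like receptors and adaptors rose in 5 of 18 cases (6 adjusted over the list alone), Tlr13 by 0.96 ± 0.19, at a median of 0.17 (camera adjusted p = 0.0102; adjusted p = 0.188 with an estimated correlation). Epithelial junction and mucin genes rose in 8 and fell in 2 of 17 cases (8 and 3 adjusted over the list alone). Their median of 0.24 and the test pointed up while the mean, pulled by Cldn2, was -0.07 (camera adjusted p = 0.0308; adjusted p = 0.341 with an estimated correlation). Absorptive colonocyte markers rose in 6 and fell in 3 of 18 cases; their median of 0.06 became -0.10 with median centring and -0.19 with the values as deposited, and the list did not pass. When the KO arrays alone were fitted, Il11, Cxcl2, Ereg and Mmp3 no longer passed (adjusted p = 0.0501, 0.0948, 0.0517 and 0.0562). The number of called genes in this comparison was then 1918, and stayed between 2801 and 4163 when any 1 array was left out.

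**Figure D3:**
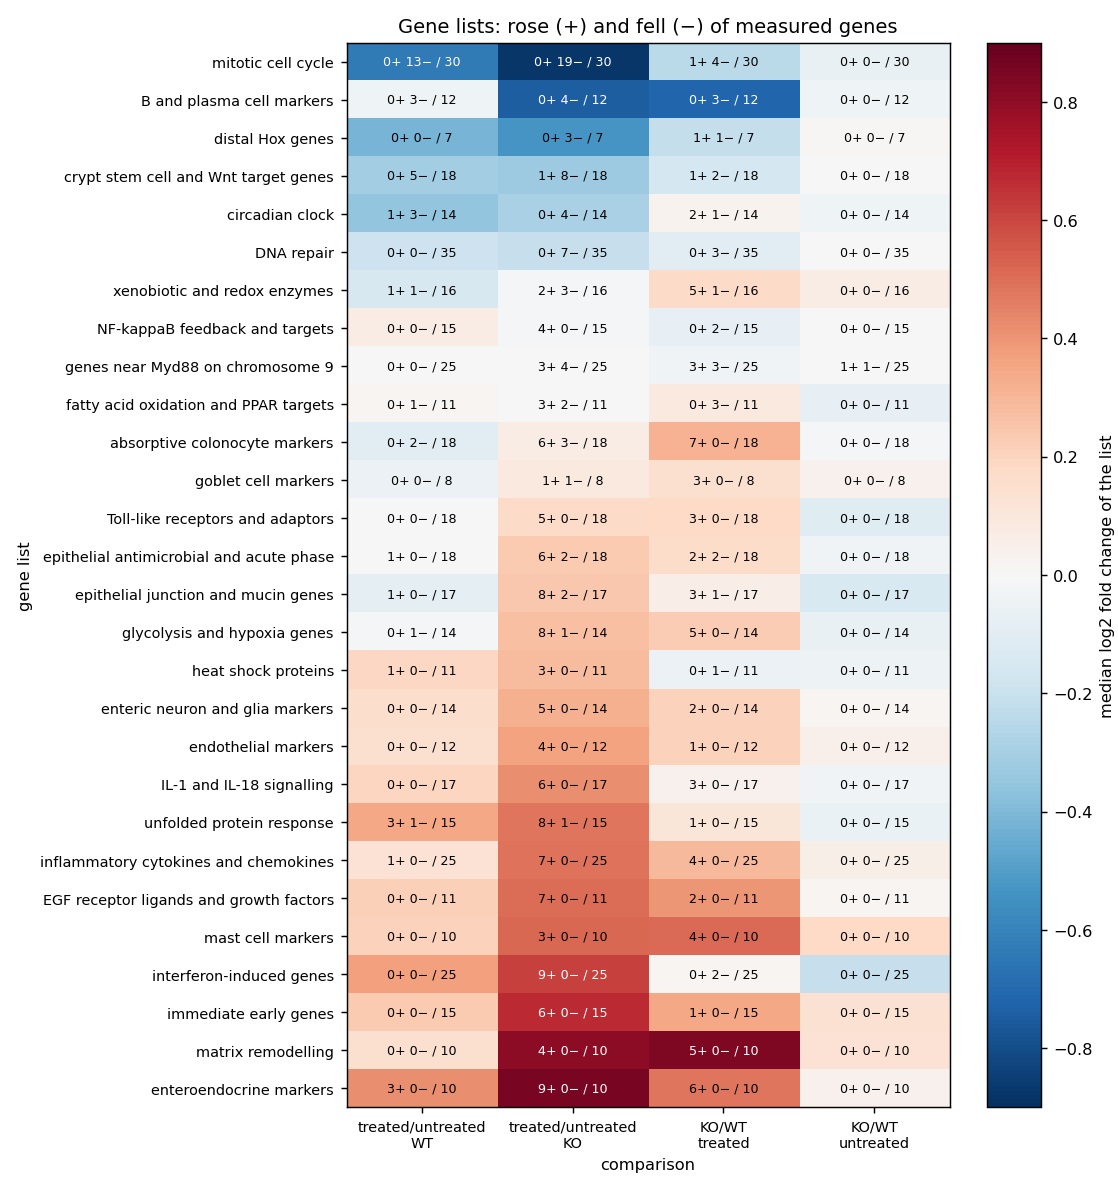
Median log2 change of each gene list (colour) in the 4 pairwise comparisons, with the number of members that rose (+) and fell (−) of those measured; lists with at least 3 called members in any of these comparisons are shown. Medians close to 0 changed sign with median centring or with the values as deposited: in the KO response those of the absorptive colonocyte, goblet, NF-kappaB, xenobiotic and fatty acid lists, between treated genotypes those of the interferon and heat shock lists, between untreated genotypes those of the DNA repair, antimicrobial, NF-kappaB, colonocyte, crypt stem cell, neuron and glia and Hox lists, and that of the genes near Myd88 in each comparison of genotypes and in the KO response.

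Treated KO and treated WT mice, whose comparison asks what Myd88 loss changed under the regimen, differed in lists of enteroendocrine, absorptive and matrix remodelling genes, which were higher in KO mice, and of B and plasma cell markers, which were lower. These list calls rest on the preset correlation between genes, and with an estimated one 0 lists passed. Over all genes 12.8% were called in this comparison, and counts of called list members are to be read against that share. The largest changes among the named genes were in Retnlb, S100g and Cldn2. Retnlb was higher in KO mice by 3.20 ± 0.87 (9.20-fold, adjusted p = 0.0147), averaging 8.73 ± 2.68 against 5.53 ± 2.07 (SD, n = 10 each). Dmp1 (2.13 ± 0.51), Khdc1a (2.01 ± 0.43), Erdr1 (1.86 ± 0.28, and 1.06 with its probe sets averaged), Mmp3 (1.82 ± 0.41) and Tmigd1 (1.81 ± 0.29) followed, and Slpi was higher by 1.76 ± 0.36. S100g, the intestinal calcium-binding protein calbindin D9k, was lower by -2.84 ± 0.48 (7.17-fold, adjusted p = 0.000354) and lay at the floor on 5 of 10 treated KO arrays. Without treatment S100g was at -2.36 ± 0.62, which did not pass (adjusted p = 0.244), with averages of 8.08 in WT and 5.72 in KO mice. Yet the untreated arrays did not overlap, at 7.55 to 8.68 in WT and 5.21 to 6.02 in KO mice. The fit shares a common spread over all groups, and the treated KO arrays ranged from 3.32 to 7.99. On these arrays S100g thus differed between genotypes without treatment too. The difference of its responses did not pass (-0.48 ± 0.78, adjusted p = 0.874). Cldn2 was lower by -2.16 ± 0.55 (4.47-fold, adjusted p = 0.00892). In a fit of the treated arrays alone the same changes of Retnlb and Cldn2 did not pass (adjusted p = 0.0672 and 0.0579). The other largest falls were in Sprr2d (-2.04 ± 0.66), Cep85 (-1.999 ± 0.178), the immunoglobulin gene Igkv4-72 (-1.997 ± 0.392) and Zan (-1.98 ± 0.35). Cep85 and Erdr1 were called in the same direction without treatment too (-1.35 ± 0.23 and 2.43 ± 0.36). The difference of the responses was called for neither, so their changes are not particular to the regimen. Cep85 is also among the clustered chromosome 4 genes described below. Sprr2d is a gene of cornifying epithelium, which moved with the squamous list. Its call (adjusted p = 0.0394) ended with the squamous and skeletal muscle means as covariates (-0.97, adjusted p = 0.229). It also ended without any 1 of treated WT repeats 1, 2, 6 and 8 and treated KO repeats 2, 4, 5, 6 and 7, at adjusted p up to 0.0809.

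Several epithelial lists were higher in treated KO than in treated WT mice. Enteroendocrine markers were higher in all 10 cases and called in 6 (8 adjusted over the list alone), at a median of 0.48 (camera adjusted p = 5.24e-06; adjusted p = 0.358 with an estimated correlation). Sst, the somatostatin gene, was higher by 0.88 ± 0.17 and Chga by 0.75 ± 0.16. Absorptive colonocyte markers rose in 7 of 18 cases (10 adjusted over the list alone) at a median of 0.31 (camera adjusted p = 2.85e-05; adjusted p = 0.311 with an estimated correlation). Slc9a3, a sodium-proton exchanger, was higher by 1.23 ± 0.28, Guca2a, the hormone guanylin, by 1.04 ± 0.19, and Fabp2 by 1.03 ± 0.19. Muc3, the brightest marker that did not pass, was at 0.02 ± 0.03 near 13.4 on the log2 scale. Goblet cell markers rose in 3 of 8 cases (5 up and 1 down adjusted over the list alone) at a median of 0.14 (camera adjusted p = 0.00951; adjusted p = 0.358 with an estimated correlation). Tff3 was higher by 0.24 ± 0.05, and by 0.48 with median centring and 0.39 with the values as deposited. Glycolysis and hypoxia genes rose in 5 of 14 cases, also adjusted over the list alone, at a median of 0.23 (camera adjusted p = 0.00022; adjusted p = 0.311 with an estimated correlation), among them Car9 (0.77 ± 0.12), Egln3 (0.69 ± 0.12) and the glucose transporter Slc2a1 (0.50 ± 0.11). The squamous list mean was lower in treated KO than in treated WT mice, as given above, and its 12 genes had a median of -1.55 with none called (camera adjusted p = 0.00182; adjusted p = 0.619 with an estimated correlation).

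Stromal and immune genes differed between the treated genotypes in both directions. Matrix remodelling genes were higher in KO mice in all 10 cases and called in 5 (7 adjusted over the list alone), at a median of 0.84 (camera adjusted p = 0.000389; adjusted p = 0.358 with an estimated correlation), with Timp1 at 1.02 ± 0.29 (adjusted p = 0.0184, and 0.0810 in a fit of the treated arrays alone). Mast cell markers rose in 4 of 10 cases (6 adjusted over the list alone) at a median of 0.51 (camera adjusted p = 0.0393; adjusted p = 0.428 with an estimated correlation). The mast cell protease genes Mcpt1 and Mcpt2 were higher by 1.65 ± 0.46 (not past in a fit of the treated arrays alone, adjusted p = 0.0789) and 1.63 ± 0.38, whereas Kit was at -0.21 ± 0.13. Cytokine and chemokine genes rose in 4 of 25 cases on both scales of adjustment, at a median of 0.29 (camera adjusted p = 0.0203; adjusted p = 0.535 with an estimated correlation). Il11 was higher by 1.77 ± 0.36 and stood above the floor on all 10 treated KO arrays and on 4 of the treated WT arrays. B and plasma cell markers fell in 3 of 12 cases (4 adjusted over the list alone) at a median of -0.71 (camera adjusted p = 0.00182; adjusted p = 0.535 with an estimated correlation). Jchain was lower by -1.54 ± 0.23 (2.90-fold, adjusted p = 0.000135), and Ccl28, a chemokine that draws IgA-producing cells to mucosa, by -0.87 ± 0.15. MHC class II genes were lower in all 8 cases at a median of -0.46 with none called (camera adjusted p = 0.0203; adjusted p = 0.574 with an estimated correlation).

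Mitotic genes fell in 4 and rose in 1 of 30 cases between treated KO and WT mice, on both scales of adjustment, at a median of -0.24 (camera adjusted p = 0.0243; adjusted p = 0.746 with an estimated correlation). Ccnb2 was lower by -0.77 ± 0.17 (adjusted p = 0.0035) and Mki67, a marker of dividing cells, by -0.71 ± 0.16 (adjusted p = 0.00474). DNA repair genes fell in 3 of 35 cases, also adjusted over the list alone, at a median of -0.10 (camera adjusted p = 0.043; adjusted p = 0.656 with an estimated correlation). These were Atm (-0.54 ± 0.09), Ddb2 (-0.55 ± 0.16) and Atr (-0.32 ± 0.08). With 12.8% of all genes called here, the counts of called mitotic and DNA repair genes alone do not set either list apart. Both lists differ between genotypes alongside the squamous list mean and the Actb 3'/5' difference given above, though not that of Gapdh (-0.40 in treated WT and -0.39 in treated KO mice), and with the 3'/5' covariate Ddb2 was at -0.48 and did not pass (adjusted p = 0.0533). Of the clock genes Per1 was higher by 0.64 ± 0.13 and Clock lower by -0.59 ± 0.08. Stem cell genes were mixed: Prom1 was higher by 1.13 ± 0.24 and Znrf3 lower by -0.52 ± 0.11 (-0.32 with its probe sets averaged). The lists of IL-1 and IL-18 signalling (3 of 17 called, camera adjusted p = 0.237) and of Toll-like receptors and adaptors (3 of 18 called, camera adjusted p = 0.0965) did not pass. Of their members, Il1rn (0.67 ± 0.12) and Ticam1 (0.54 ± 0.12) were higher in KO mice, as were Irak1 (0.49 ± 0.13) and Tlr4 (0.45 ± 0.12). Irak1 did not pass with the squamous and skeletal muscle means as covariates (0.44, adjusted p = 0.0572), nor did Tlr4 with its probe sets averaged (0.25, adjusted p = 0.0644).

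In all, 2331 genes differed between the treated genotypes, 1135 higher and 1196 lower in KO mice, and 117 by at least 2-fold. The share higher was 48.7%, but 74.1% with median centring and 41.8% with the values as deposited, so the balance of rises and falls rests on the scaling. The count was 1427 with the squamous and skeletal muscle means as covariates, 1703 without treated WT repeats 1 and 2, and 1338 when the treated arrays alone were fitted.

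Without treatment the genotypes differed in 21 genes, 7 higher and 14 lower in KO mice, and 9 by at least 2-fold (limma), with 1303 genes at an unadjusted p under 0.05 where chance gives 909.65. Besides Myd88, the largest falls were in Efhd2, a calcium-binding actin regulator (-2.30 ± 0.15, 4.93-fold, adjusted p = 6.7e-11), Dcdc2b (-1.54 ± 0.19), Cep85 (-1.35 ± 0.23), Nckap5l (-1.34 ± 0.27), Snhg3 (-1.01 ± 0.20) and A4galt (-0.98 ± 0.21). The largest rises were in Erdr1 (2.43 ± 0.36), Ptp4a2, a tyrosine phosphatase (1.59 ± 0.13, 3.01-fold, adjusted p = 4.84e-09), Itga9, an integrin subunit (1.49 ± 0.18), Tmppe (1.24 ± 0.14), Clasp2 (0.78 ± 0.12) and Tmem234 (0.39 ± 0.08). Each of these 13 named genes differed in the same direction on all 6 KO arrays from the WT mean. When the probe sets of a gene were averaged, the calls of Itga9 and Ptp4a2 ended (0.71 and 0.55, adjusted p = 0.314 and 0.102), and the changes of Erdr1 (1.59), Tmppe (0.63) and Clasp2 (0.46) were smaller and still passed. The call of A4galt (adjusted p = 0.0465) ended in 24 of the 32 fits that left out 1 array, at adjusted p up to 0.160, and it passed in 14 of 45 settings overall. The call of Nckap5l ended in 9 of these fits and those of Snhg3 and Tmem234 in 6 each, always without 1 of the untreated arrays, at adjusted p up to 0.0880. Tmem234 did not pass with median centring (0.37, adjusted p = 0.551) or with the values as deposited (0.38, adjusted p = 0.0622), Snhg3 with the 3'/5' covariate (-0.95, adjusted p = 0.0522) or the repeat number as a block (adjusted p = 0.0936), and Nckap5l in a fit of the untreated arrays alone (adjusted p = 0.121), with median centring (-1.21, adjusted p = 0.0590) or the block (adjusted p = 0.0597).

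Between the untreated genotypes 2 lists passed. Interferon-induced genes had a median of -0.21 and 22 of 25 were lower in KO mice, with none called and none adjusted over the list alone (camera adjusted p = 0.0264; adjusted p = 0.999 with an estimated correlation). Cholesterol biosynthesis genes had a median of 0.14 with 14 of 15 higher and none called on either scale (camera adjusted p = 0.0264; adjusted p = 0.999 with an estimated correlation). Oas1a and Hmgcs1, the brightest genes of these lists, were at -0.17 ± 0.20 and 0.04 ± 0.14. Of the 21 genes, 16 also differed between the treated genotypes and 15 of them in the same direction (6 up and 9 down, against 0.437 and 0.920 by chance). Apart from Myd88 and Erdr1, these 15 all lay on chromosome 4 or close to Myd88 on chromosome 9, a pattern taken up below. Of the 6 called genes on other chromosomes only Erdr1 kept its call and direction, and A4galt was called the other way (0.68 ± 0.16). The overlap thus rests mainly on the clustered genes. Of the 2331 genes called between treated genotypes, 67.2% had the same sign without treatment, at a median size of 0.38 with treatment and 0.060 in that direction without it. Across all 18193 genes, the genotype effects with and without treatment correlated with Pearson r = 0.146 and Spearman rho = 0.164; genes are not independent replicates.

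The responses of the genotypes ran in the same direction for most called genes. All 236 genes called in both responses moved the same way (74 up and 162 down, against 9.56 and 22.2 by chance), and 318 of the 332 genes called in WT mice had the same sign in KO mice (95.8%). For those 332 genes the median size was 0.63 in WT mice, where they were chosen, and 0.57 in KO mice in the WT direction. For the 3404 genes called in KO mice it was 0.48 there and 0.17 in WT mice in the KO direction, with 2928 of the same sign (86.0%) and 130 larger in WT mice. Each set is favoured where it was chosen. Across all genes, which are not independent replicates, the responses correlated with Pearson r = 0.523 and Spearman rho = 0.470.

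**Figure D4:**
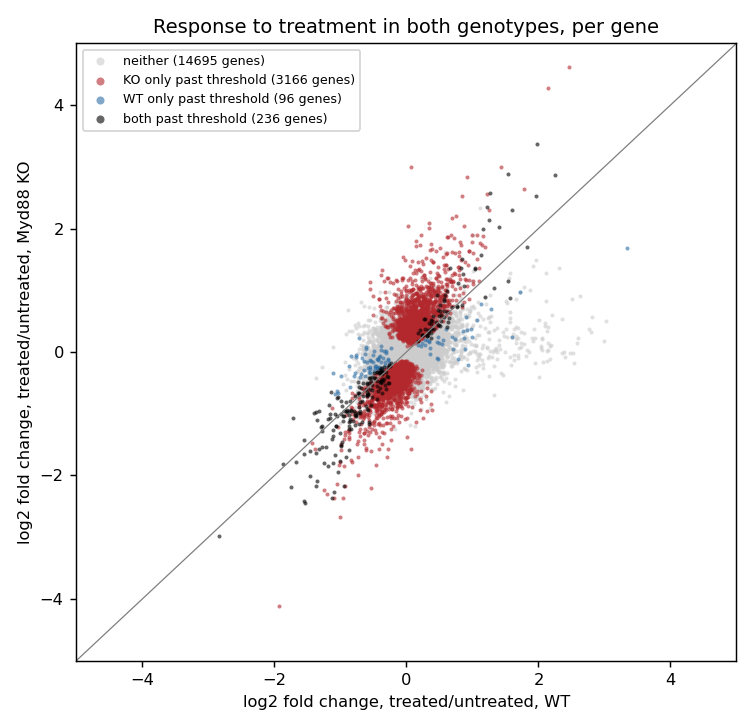
Log2 change with treatment of each of 18193 genes in WT mice (horizontal) and in KO mice (vertical), coloured by the comparison in which the gene was called, with the line of equal change. All 236 genes called in both genotypes lie in the quadrants of equal sign.

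The test of the difference between the responses itself called 10 genes, 9 of them up, at adjusted p under 0.05 (limma), with 2128 at an unadjusted p under 0.05 where chance gives 909.65. A4galt, a glycosyltransferase gene, changed by 1.67 ± 0.26 more in KO than in WT mice (adjusted p = 0.0106). Nckap5l (1.69 ± 0.34, adjusted p = 0.0468), the transcription factor gene Maff (1.28 ± 0.23, adjusted p = 0.0223) and Egln3, an oxygen-sensing prolyl hydroxylase gene (1.02 ± 0.20, adjusted p = 0.0468), followed. For Nckap5l, KO minus WT was -1.34 ± 0.27 without treatment and 0.35 ± 0.21, not called, with it. Its value thus came mostly from the untreated arrays, and all untreated KO arrays except repeat 4 lay at or near the floor (3.32 to 3.67). Anapc2, a subunit of the anaphase-promoting complex, changed by -0.36 ± 0.07 (adjusted p = 0.0468). The calls of Nckap5l, Egln3 and Anapc2 each ended in 25 of the 32 fits that left out 1 array, at adjusted p up to 0.128, and that of Maff without any 1 of untreated WT repeats 4 and 5 and untreated KO repeats 1, 2 and 3, at adjusted p up to 0.0706. With the squamous and skeletal muscle means as covariates Nckap5l (1.52), Maff (1.15), Egln3 (1.05) and Anapc2 (-0.38) did not pass (adjusted p between 0.0545 and 0.160). Anapc2 was at -0.25 with median centring (adjusted p = 0.388). The count moved from 10 to 164 without treated KO repeat 9 and to 36 without treated KO repeat 6. It fell to as low as 3, without untreated WT repeat 4. With the squamous and skeletal muscle means it was 2, and at an adjusted p under 0.01 it was 0. On the first principal component of the gene signals treated KO repeat 9 stood at 23.0. The treated KO median was -26.7 there and the untreated KO median 24.4. Why this array stands apart was not tested.

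For the difference of the responses 12 lists passed camera, and none of them did with an estimated correlation. Glycolysis and hypoxia genes responded more strongly upward in KO mice by a median of 0.28, with 1 called and 5 adjusted over the list alone (camera adjusted p = 5.12e-05; adjusted p = 0.156 with an estimated correlation). Absorptive colonocyte markers had a median of 0.41 with none called and 4 adjusted over the list alone (camera adjusted p = 0.000195; adjusted p = 0.444 with an estimated correlation), and enteroendocrine markers 0.45 with none called and 1 adjusted over the list alone (camera adjusted p = 0.000521; adjusted p = 0.593 with an estimated correlation). The squamous list, at a median of -1.79 with none called on either scale, was the most negative of the lists that passed (camera adjusted p = 0.00235; adjusted p = 0.607 with an estimated correlation), and B and plasma cell markers followed at -0.61 with none called on either scale (camera adjusted p = 0.0168; adjusted p = 0.597 with an estimated correlation).

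Of the 14 core genes measured, 3 were called between treated genotypes, 1 higher and 2 lower in KO mice, and 1 between untreated genotypes. Over all genes 12.8% and 0.115% were called in these comparisons. Myd88, the targeted gene, was the untreated call and 1 of the 2 lower treated calls, so its part in these counts was given by the design. The other treated calls were Ptgs2 and Nnt. Ptgs2, the inducible cyclooxygenase, was higher in treated KO than WT mice by 1.12 ± 0.35 (adjusted p = 0.0303), a call that ended without any 1 of treated WT repeats 6 and 8 and treated KO repeats 2 and 4, at adjusted p up to 0.0687, and in a fit of the treated arrays alone (adjusted p = 0.108). Nnt, a mitochondrial transhydrogenase, was lower by -0.42 ± 0.10 at its brightest probe set, but by -0.055 with its probe sets averaged (adjusted p = 0.782). In KO mice treatment raised Il18 by 0.42 ± 0.10 (adjusted p = 0.00448), Il18bp, which binds and blocks IL-18, by 1.23 ± 0.37 (adjusted p = 0.0191), Ptgs2 by 1.33 ± 0.40 and Ereg by 1.88 ± 0.48, and lowered Nnt by 0.58 ± 0.12 (adjusted p = 0.0012; by 0.32 with its probe sets averaged, adjusted p = 0.0266). In WT mice Nnt was at -0.31 ± 0.12 (adjusted p = 0.204). In a fit of the KO arrays alone Il18bp, Ptgs2 and Ereg did not pass (adjusted p = 0.0791, 0.122 and 0.0517). Il18bp lost its call without untreated KO repeat 1 or 2, at adjusted p up to 0.0724. Myd88 itself rose by 0.33 ± 0.10 (adjusted p = 0.0225), a call that ended without untreated KO repeat 2 or 5, at adjusted p up to 0.0598, and in a fit of the KO arrays alone (adjusted p = 0.121). The antimicrobial lipocalin gene Lcn2 rose by 1.10 ± 0.39 in KO mice (adjusted p = 0.0478), which ended in 26 of the 32 fits that left out 1 array, and was at 1.01 ± 0.39 in WT mice (adjusted p = 0.198). In WT mice Il18 was at 0.30 ± 0.10 (adjusted p = 0.139) and Ereg at 1.16 ± 0.48 (adjusted p = 0.234). Il1b, Tnf, Reg3b and Saa1 did not pass in any comparison. Il6 lay at the floor on all arrays except 3 of treated KO mice, and Nos2 and Reg3g are listed at the floor on all 32 arrays.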

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

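Tests chosen only after the result was seen were those of gene position and of strain variants under the probes, the tissue and 3'/5' covariates for the number of genes that differed between treated genotypes, and the test of the epithelial share. The other tests were set before their result was seen. The squamous and skeletal muscle covariates used for the mitotic genes were themselves chosen after the data were seen.

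The first pattern is that genes differing between untreated genotypes lay close together in the genome. Of the 20 called genes besides Myd88, 5 (Glb1, Ctdspl, Clasp2, Tmppe and Itga9) lay within 100 tested genes of Myd88 on chromosome 9, where 0.193 were expected (one-sided Fisher p = 1.09e-06), and 8 lay in a single window of 200 tested genes on chromosome 4, where 10000 random sets gave a median of 2 and at most 5 (permutation p = 1e-04, the smallest these draws can give). A candidate explanation is DNA of the donor strain, carried along with the targeted gene and in a second segment, and the labels' background of at least 98% leaves room for it. Strain variants under the probes stay open: of 10 genes with another bright probe set, all such probe sets moved the same way for 5. That criterion replaced an earlier and weaker one, any agreeing probe set, which gave 8 of 10 and would have spoken against the explanation; the change was made after that result was seen, because probe sets of a gene can share variants.

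The second pattern is that 2331 genes differed between treated genotypes and 21 between untreated ones. Of 100 draws of 6 treated arrays per genotype, 0 gave 21 or fewer, with a median of 988.5 and a range of 84 to 3354. Fewer untreated arrays alone thus do not give the gap in a fit of all groups. The draws kept the untreated arrays in that fit with a shared spread, so they cannot separate array number from unequal spread between groups. In fits of the compared groups alone 1338 treated and 28 untreated genes passed. With the squamous and skeletal muscle means as covariates 1427 treated genes passed and 23 untreated, so these means alone are not the whole cause. With the 3'/5' difference as a covariate 1599 and 22 passed. That covariate averages the Actb and Gapdh controls, which do not agree and were not fitted separately, so it cannot exclude a difference in RNA integrity. A difference in how KO mice react to the regimen may lie behind it, as a hypothesis; the test of that difference itself called 10 genes. Different exposure, collection day or housing of the treated groups is not given in the labels and was not tested.

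The third pattern is that mitotic genes were lower in treated mice of both genotypes, at medians of -0.64 and -0.87. A lower epithelial share of the tissue would lower epithelial markers alike, but the 43 genes of the epithelial lists had medians of -0.083 (SD 0.47) in WT and 0.11 (SD 0.79) in KO mice, although many of them lie near the top of the scale. In KO mice the colonocyte and goblet medians became -0.10 and -0.090 with median centring, and -0.19 and -0.18 with the values as deposited. Changes of these markers within cells could also hide a lower share, so the test cannot exclude one. With the 3'/5' covariate 91.8% of the WT median was kept, and with the squamous and skeletal muscle means 115%, while the number of called WT members dropped from 13 to 5 and 6, for a reason that was not tested. As the 3'/5' covariate averages controls that do not agree, it leaves a difference in RNA integrity open here too. Fewer dividing cells in the crypts after treatment may be the source, as a hypothesis found and examined on the same arrays. The same mice received AOM and then DSS, and the labels give no protocol for the untreated mice, so neither the shares of AOM and DSS nor other differences in handling can be separated in this design.

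Splits of the arrays into groups of the same sizes were drawn 100 times for each comparison, the real split included. In each of the 5 comparisons 1 split, the real one, gave as many genes. For the pairwise comparisons no random split thus reached the real count. For the difference of the responses the splits shuffled genotype within treated and within untreated arrays. That also removes the genotype effects themselves, so these splits cannot tell whether its 10 genes exceed chance. The real counts were 2331 (treated genotypes), 21 (untreated genotypes), 332 (WT response), 3404 (KO response) and 10 (difference of the responses), and the highest of the other splits gave 625, 2, 5, 1657 and 1.

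A test of the difference between the responses singled out 10 genes and 12 gene lists. Those named were A4galt (1.67), Nckap5l (1.69), Maff (1.28), Egln3 (1.02) and Anapc2 (-0.36). A4galt and Nckap5l were also called between untreated genotypes, lower in KO mice. A4galt passed in all 44 fits examined, with adjusted p between 0.000791 and 0.0421; the calls of Nckap5l, Egln3 and Anapc2 each ended in 25 of the 32 fits without 1 array, at adjusted p up to 0.128, and that of Maff without any 1 of untreated WT repeats 4 and 5 and untreated KO repeats 1, 2 and 3, at adjusted p up to 0.0706.

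Single arrays stood apart from the rest of their group in 15 of 234 sets of values, where chance gives about 11.7. Treated WT repeat 2 did so for Cxcl5 (9.82, others 5.77 to 7.82), Il1b (6.86, others 5.26 to 6.03) and A4galt (5.25, others 5.68 to 6.16). Treated KO repeat 9 did so for Otc (6.54, others 3.32 to 4.79) and Lpcat4 (4.25, others 6.24 to 7.91), and untreated WT repeat 3 for the skeletal muscle mean (9.66, others 4.72 to 5.25) and Acacb (4.90, others 3.32 to 3.82). The remaining ones were Acacb in treated WT repeat 1 (7.24, others 4.45 to 5.75), Erdr1 in treated WT repeat 4 (8.81, others 5.90 to 6.81), Slpi in treated KO repeat 6 (8.61, others 10.7 to 12.4), Zan in untreated KO repeat 5 (3.67, others 5.32 to 6.22), Nckap5l in untreated KO repeat 4 (4.85, others 3.32 to 3.67), Sptssb in untreated WT repeat 1 (5.18, others 3.32 to 3.79), Reg3b in untreated WT repeat 4 (3.32, others 4.58 to 5.12) and Cttnbp2 in untreated WT repeat 6 (8.62, others 9.14 to 9.31). Outside this count, treated KO repeat 9 lay near the untreated KO arrays for Cldn2 (9.82, untreated KO 9.71 to 10.2). The same held for Ascl2 (6.59, untreated KO 6.69 to 7.06) but not for Slpi (10.7, untreated KO 7.29 to 9.33).

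Probe sets without a single gene symbol were outside the comparisons of genes. Of 10092 such probe sets 501 differed between treated genotypes, 125 higher and 376 lower in KO mice, and 22 between untreated genotypes.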

How the results depend on the processing

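Alternatives chosen only after the data were seen were the values as deposited, the squamous and skeletal muscle means as covariates, the fit without treated WT repeats 1 and 2, and the Xist covariate. Quantile normalization as an alternative was not run because it was already in use, and a different pseudocount was not run because the values were on a log2 scale. Where a count moved and no reason is given, the cause was not tested.

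For the difference of the responses, the count of 10 became 20 with median centring, 18 with averaged probe sets, 3 with the repeat number as a block, 258 with array weights, 55 with the 3'/5' covariate, 23 with the smooth muscle covariate, 6 with the values as deposited, 2 with the squamous and skeletal muscle covariates, 3 without treated WT repeats 1 and 2, and 5 with the Xist covariate. The labels do not say that equal repeat numbers pair mice, and residuals of arrays that share a number correlated with r between -0.17 and 0.34, so the block was not used further. In the WT response the count of 332 became 185 with median centring (176 shared with the 332), 1458 with array weights (332 shared), 159 with the 3'/5' covariate (155 shared), 208 with the squamous and skeletal muscle covariates (167 shared) and 888 in a fit of the WT arrays alone. Between treated genotypes, the count of 2331 became 1427 with the squamous and skeletal muscle covariates and 1338 in a fit of the treated arrays alone. The KO response count of 3404 became 1918 in a fit of the KO arrays alone. Between untreated genotypes, the count of 21 became 43 with array weights. The difference of the responses has no fit of fewer groups.

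Stricter thresholds count fewer genes by construction. Changes of at least 2-fold were counted in 117 (treated genotypes), 9 (untreated genotypes), 75 (WT response), 382 (KO response) and 4 genes (difference of the responses). At an adjusted p under 0.01, 1005, 13, 67, 1823 and 0 genes passed in limma; for the last, 2128 had an unadjusted p under 0.05.

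Without any 1 array, the counts ranged from 1775 to 3026 between treated genotypes, from 15 to 29 between untreated genotypes, from 165 (without untreated WT repeat 6) to 445 (without treated KO repeat 9) in the WT response, from 2801 to 4163 in the KO response, and from 3 (without untreated WT repeat 4, or untreated KO repeat 1 or 2) to 164 (without treated KO repeat 9) for the difference of the responses. The last count moved by more than 1.5 times in 24 of 32 fits, upward without treated KO repeats 6 (36) and 9 and treated WT repeat 9 (18).

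With an estimated correlation, 0 lists passed in each of the 5 comparisons, where 15, 2, 20, 24 and 12 of 41 passed at the preset correlation. With fry, 0 passed between untreated genotypes, 6 in the WT response and 1 for the difference of the responses. Leaving out dim genes gave 9 between treated genotypes, 15 in the KO response and 7 for the difference of the responses, and the squamous and skeletal muscle covariates gave 1 between untreated genotypes. Of the 73 list results, 34 no longer passed with fry, 18 of 69 without dim genes, 16 with the squamous and skeletal muscle covariates, 10 with median centring, 7 with the values as deposited, 6 each with the smooth muscle covariate and without treated WT repeats 1 and 2, and 2 with the block. None changed direction. Lists lower in treated KO than WT mice numbered 5, and 2 with the squamous and skeletal muscle covariates, without treated WT repeats 1 and 2, or without dim genes.

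The correlation of the genotype effects rose from 0.146 to 0.243 without dim genes and to 0.438 among genes called in either comparison, and that of the responses from 0.523 to 0.636 and 0.788. The last subset was picked for the size of its effects.

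Of the named gene results, 62 of 212 no longer passed in fits of the compared groups alone. Of all 217, 40 no longer passed with the 3'/5' covariate, 31 with the squamous and skeletal muscle covariates, 22 each with the block and without treated WT repeats 1 and 2, 19 with median centring, 18 with the values as deposited, 17 with averaged probe sets, 11 with the smooth muscle covariate, 6 with array weights, 4 with the Xist covariate and 1 with the trended prior. Without dim genes 2 of 179 no longer passed. For 54 of them at least 1 single array ended the call. None changed direction in the settings counted here. Dim genes at the floor of the signal are the limit of depth on these arrays.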

Other observations

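The gene families below were chosen after their values were seen, and no test was run on them as sets; their values are those after quantile normalization, and other scalings were not tried for them.

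Of 23 immunoglobulin genes measured, 6 fell in treated WT mice, at a family median of -0.87, and 12 in treated KO mice, at -1.18, and the others were not called; 9 were lower and 1 higher in treated KO than treated WT mice. In the KO response 10 of 18 glutathione S-transferase genes fell at a median of -0.32, with Gsta3 at -2.30, and 23 of 76 mitochondrial ribosomal protein genes fell and 1 rose, at a median of -0.21; most members of the second family were not called. Over all genes 18.7% were called in this response. Of other detoxifying families, 12 of 73 cytochrome P450 genes fell and 1 rose, 3 of 13 carboxylesterase genes fell and 1 rose, and 2 of 11 UDP-glucuronosyltransferase genes fell. In the WT response 1 glutathione S-transferase gene rose, and no mitochondrial ribosomal protein gene was called by limma. For neither family was the difference between the responses called in any member.

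Other lists with called members were mixed. Epithelial antimicrobial and acute phase genes rose in 6 and fell in 2 of 18 cases in the KO response at a median of 0.24 (camera adjusted p = 0.0348; adjusted p = 0.288 with an estimated correlation). In the same response endothelial markers rose in 4 of 12 cases at a median of 0.36 (camera adjusted p = 0.00204; adjusted p = 0.347 with an estimated correlation), enteric neuron and glia markers in 5 of 14 at 0.32 (camera adjusted p = 0.00141; adjusted p = 0.288 with an estimated correlation), glycolysis and hypoxia genes in 8 of 14 with 1 fall at 0.27 (camera adjusted p = 0.000943; adjusted p = 0.159 with an estimated correlation), and heat shock proteins in 3 of 11 at 0.28 (camera adjusted p = 0.0361; adjusted p = 0.364 with an estimated correlation). Neutrophil markers rose in 2 of 14 cases in the KO response at a median of 0.24 (camera adjusted p = 0.0444; adjusted p = 0.341 with an estimated correlation). Over all genes 18.7% were called in that response, so this count does not set the list apart. In the WT response all 13 smooth muscle markers were higher, with none called, at a median of 0.22 (camera adjusted p = 0.00314; adjusted p = 0.467 with an estimated correlation), and unfolded protein response genes rose in 3 and fell in 1 of 15 cases at a median of 0.35 (camera adjusted p = 0.0015; adjusted p = 0.227 with an estimated correlation).

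Lists that did not pass in any comparison were p53 targets, NF-kappaB feedback and targets, T and NK cell, eosinophil, fibroblast and collagen and adipocyte markers, xenobiotic and redox enzymes, fatty acid oxidation and PPAR targets, genes near Myd88, and sex-linked genes. In the KO response their medians were 0.18, -0.012, 0.15, 0.047, 0.18, 0.70, -0.016, 0.0037, 0.0017 and 0.081 in that order. Those of the NF-kappaB, xenobiotic, fatty acid and near-Myd88 lists changed sign with another scaling. The list test asks for a shift in a single direction. Called members of the near-Myd88 list went both ways between untreated genotypes (Itga9 at 1.49 and Ctdspl at -0.89). Its result therefore does not speak against differences among these genes.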
